A study of Homo sapiens with 23 samples.

How the data were processed

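RNA from 3 HOSE, 10 LGOV and 10 HGOV samples was labelled with biotin and read on Affymetrix one-colour arrays with 54675 probe sets. The deposited values are intensities on a linear scale, 1 per probe set and array, as the values themselves show: the lowest is 1 and the highest 15261. Software for background correction, summarisation and normalization is not given in the sources used here. Groups and replicate numbers were taken from the sample titles in the labels, and 0 pairs of arrays held identical values.

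The 62 control probe sets were left out of the tests, which leaves 54613. Of these, 41091 have 1 gene symbol in the platform annotation, 1801 have several and 11721 have none, and no gene was named from the last 2 classes. Entrez identifiers of 41037 probe sets were found in the RefSeq table, and 0 symbols needed an update. For a gene with several probe sets, the probe set with the highest mean log2 value over all arrays stands for it, which gives 19775 genes. Some genes fixed in advance are not reported here.

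Values below the 10th percentile of the table, an intensity of 34.4 (log2 5.11), were raised to that floor and all were log2 transformed. A fold against a group wholly at the floor is a lower bound. Array medians differed by less than 1 log2 unit, so no further normalization was applied, as fixed before the data were examined. Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on all 23 arrays in 1 fit, with Benjamini-Hochberg adjustment over all probe sets, two-sided, at an adjusted p under 0.05. PAX2 was also tested by a two-sided permutation test of the mean difference, exact over 286 splits with HOSE and with 100000 resamples between the tumour grades. The 25 gene lists were tested with limma's camera at a preset correlation of 0.01, beside an estimated correlation and fry, and 586 of their 635 entries had a probe set. Camera called 7, 15 and 11 lists for HGOV against LGOV, LGOV against HOSE and HGOV against HOSE, fry called 9, 20 and 19, and camera with an estimated correlation called 0 in each. Under varied settings the lists were tested by camera with the preset correlation only.

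Named genes followed a rule fixed before the data were examined: per comparison the 8 largest changes upward and 8 downward among those past the threshold, up to 4 members with the smallest adjusted p of each list described, and genes fixed in advance. Settings varied were quantile normalization, median centring, floors, a filter on dim probe sets, separate fits of 2 groups, the trend, robust fitting, array weights, a replicate block, each array left out in turn, a stricter threshold and genes in place of probe sets. Settings added after the data were seen left out or adjusted for HGOV arrays with a log2 3' to 5' ratio above 2, and for 5 HGOV arrays at one end of the first principal component of 27 bacterial control probe sets (33.9% of variance). The gap that sets these 5 arrays off, 0.54, was little larger than the next gap, 0.44, which lies within the set. On these control probe sets alone the split is a weak one. The same 5 arrays, HGOV replicates 6 to 10, also had the lowest median intensities of the tumour arrays. These were 93.4 to 98.1, where the lowest of the other tumour arrays, LGOV replicate 3, read 98.5.

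The scripts were tested on simulated arrays with the real means and spread and 200 changed probe sets among 54613. At a simulated 2-fold change, 84.5% were recovered for HGOV against LGOV, 71.0% for LGOV against HOSE and 69.5% for HGOV against HOSE. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.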

Results

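Gene expression was measured with Affymetrix one-colour arrays in 3 samples of normal human ovarian surface epithelium (HOSE), 10 low-grade serous ovarian carcinomas (LGOV) and 10 high-grade serous ovarian carcinomas (HGOV). The series concerns PAX2, a transcription factor of Mullerian duct and kidney development, as a marker of low-grade disease. The median intensity was 68.9 ± 1.56 (SD, n = 3) in HOSE, 102 ± 2.16 (SD, n = 10) in LGOV and 98.7 ± 3.53 (SD, n = 10) in HGOV. The number of arrays limits the precision of every value, and the labels do not say from how many donors the samples of a group came.

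The arrays also differed in technical measures. The ratio of 3' to 5' control probe sets for beta-actin and GAPDH, which rises when RNA is degraded or shortened in labelling, averaged 0.08 ± 0.06 log2 units in HOSE (SD, n = 3), 1.01 ± 0.37 in LGOV (SD, n = 10) and 1.63 ± 1.28 in HGOV (SD, n = 10). HGOV replicates 2, 4 and 6 stood at 3.99, 2.72 and 3.53. The bacterial dap transcript, which is added to RNA before labelling, read 7.90 ± 0.20 log2 units in HOSE (SD, n = 3) against 3.18 ± 0.29 in LGOV and 3.40 ± 0.29 in HGOV (SD, n = 10 each). Labelling run and tissue therefore cannot be told apart in any comparison with HOSE.

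**Figure D1:**
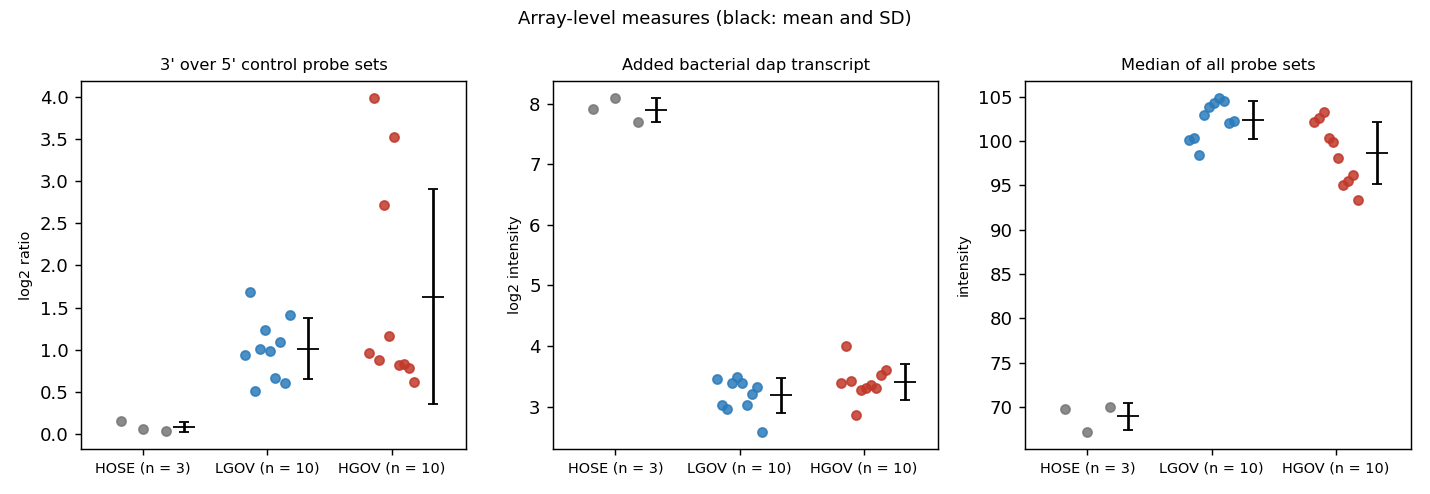
Array-level measures for 3 HOSE, 10 LGOV and 10 HGOV samples: the log2 ratio of 3' to 5' control probe sets, the log2 intensity of the added dap transcript and the median intensity of all probe sets. Points are arrays and black bars are the mean and SD; the HOSE arrays lie apart in all panels, and HGOV replicates 2, 4 and 6 have ratios of 3.99, 2.72 and 3.53.

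The first comparison asked whether PAX2 separates low-grade from high-grade tumours. Both PAX2 probe sets read higher in LGOV than in HGOV. They are called here the specific probe set, whose probes match PAX2 alone by the naming of the array, and the x probe set, whose name marks probes that can also match other transcripts. On the specific probe set, PAX2 averaged 7.34 ± 1.78 log2 units in LGOV (SD, n = 10) and 5.74 ± 0.86 in HGOV (SD, n = 10), a 3.03-fold difference (log2 difference of HGOV minus LGOV -1.60, SE 0.58, two-sided permutation p = 0.0218, limma adjusted p = 0.0489). The low-grade tumours were not uniform: 5 of 10 lay above the highest HGOV value, with intensities up to 967, whereas 2 of 10 were at the floor set for dim values. In HGOV the highest intensity was 227, in replicate 1, and 2 of 10 arrays were at the floor. On the x probe set, which had the higher mean and was the main probe set by rule, PAX2 averaged 7.01 ± 0.18 in LGOV and 6.67 ± 0.14 in HGOV (SD, n = 10 each), a log2 difference of -0.33 (SE 0.07, two-sided permutation p = 0.00016, limma adjusted p = 0.00552). The call on the specific probe set was lost at the same difference in a fit of 2 groups (limma adjusted p = 0.0649), without the mean-variance trend (limma adjusted p just above the threshold) and with the replicate block (limma adjusted p = 0.0743). Without HGOV replicates 6 to 10, which lay at one end of a control probe component and were left out after the data were seen, the difference on the specific probe set was -1.31 (two-sided permutation p = 0.156). With that split as a covariate the x probe set read -0.26 (limma adjusted p = 0.138).

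In HOSE, PAX2 on the specific probe set was at the floor in all 3 samples. LGOV read 2.23 log2 units above it (limma adjusted p = 0.0239). HGOV read 0.63 above it (limma adjusted p = 0.536), or 0.40 without HGOV replicate 1. The exact permutation test could not pass there, since 2 arrays of each grade were also at the floor. With these ties both differences had the smallest two-sided p it could give, exact permutation p = 0.0699. With a floor of 1 in place of the 10th percentile the differences were 2.98 and 1.36, each with an exact two-sided permutation p = 0.00699. That separation rests on dim signal: HOSE intensities were 19.3 to 21.4, and the lowest in LGOV and HGOV were 32.1 and 28.3. Array medians were also lower in HOSE (68.9, against 102 in LGOV and 98.7 in HGOV). A shift of whole arrays may therefore account for it. On the x probe set, HOSE averaged 6.27 ± 0.02 (SD, n = 3). LGOV exceeded it by 0.74 and HGOV by 0.41, each with an exact two-sided permutation p = 0.00699, the smallest that 3 against 10 samples allow. These last differences depended on array scaling: after quantile normalization LGOV exceeded HOSE by 0.18 (exact permutation p = 0.126) and the HGOV difference changed sign to -0.10 (exact permutation p = 0.203).

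**Figure D2:**
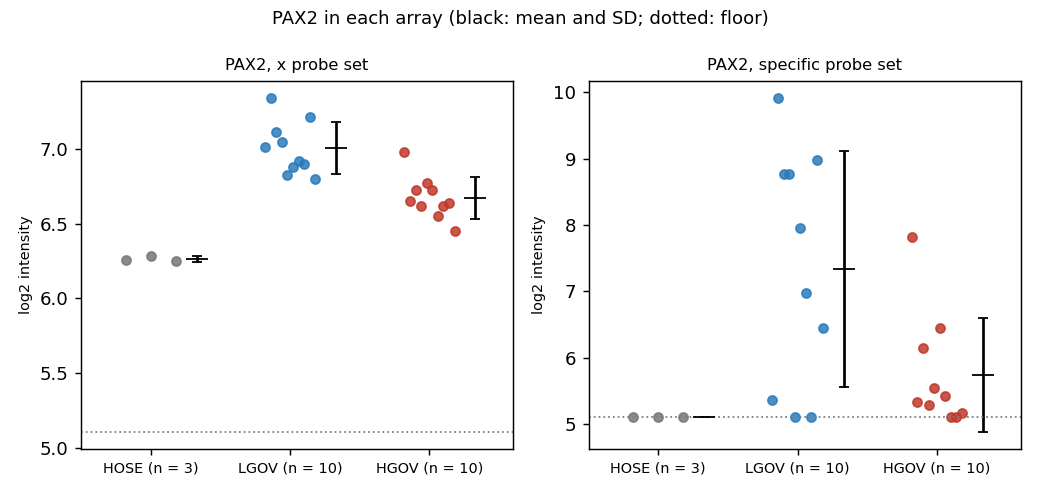
PAX2 log2 intensity of each array by group for the x probe set (left) and the specific probe set (right); points are arrays (3 HOSE, 10 LGOV, 10 HGOV), black bars are the mean and SD, and the dotted line is the floor at 5.11. On the specific probe set, 5 of 10 LGOV arrays lie above the highest HGOV array and the 3 HOSE arrays lie at the floor.

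Across the genome, the clearest differences between grades were higher interferon-induced and cell division genes in HGOV. Among genes of the type I interferon response, the antiviral programme switched on by interferon alpha and beta, 15 of 32 rose and none fell (18 higher and 1 lower when adjusted over the list alone), with a median log2 change of 0.76. ISG15, a ubiquitin-like modifier, rose 6.21-fold (log2 2.63, SE 0.39, limma adjusted p = 0.00176), BST2, which tethers virions, by 2.40, IFI6 by 2.28, IFI44L by 1.92, MX1 by 1.61 and MX2 by 1.11 log2 units. The list differed from other genes in limma's camera test with a preset correlation (adjusted p = 1.81e-10) but not with an estimated correlation (adjusted p = 0.369). The size of the change differed between sets of HGOV arrays. The median was 1.09 without HGOV replicates 6 to 10, which lay at one end of a control probe component, and 0.34 with only those. The list was called in both cases with the preset correlation (camera in limma adjusted p = 7.83e-26 and 0.00667).

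Proliferation genes were higher in HGOV in 24 of 40 cases and lower in none (29 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.65. NUSAP1, a spindle protein, rose by 1.64 (SE 0.39, limma adjusted p = 0.00899), CDC20, an activator of the anaphase-promoting complex, by 1.45, UBE2C by 1.43, ZWINT by 1.35, TOP2A by 1.09 and the kinetochore gene NDC80 by 0.90 log2 units. The main probe set of MKI67 read -0.35 (limma adjusted p = 0.0506), while 3 of its other probe sets were higher, and the mean over its probe sets was 0.29 (limma adjusted p = 0.0228). Of 30 genes of DNA replication licensing and E2F targets, 12 rose and 4 fell (16 and 4 adjusted over the list alone). GINS1 rose by 1.20, RFC4 by 0.87, CCNE1, the cyclin of S phase entry, by 0.84 and CDT1 by 0.53. Camera gave adjusted p = 2.45e-14 for proliferation and adjusted p = 3.76e-06 for replication with the preset correlation in limma, and adjusted p = 0.369 for each with an estimated correlation. The median of the replication list was 0.37 with all arrays and 0.22 without HGOV replicates 6 to 10. There it was still called with the preset correlation (camera in limma adjusted p = 6.92e-05).

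Genes reported as gained in high-grade tumours were higher in 7 of 17 cases and lower in 1 (7 and 1 adjusted over the list alone), including MYCL by 1.15, PRKCI, an atypical protein kinase C, by 1.04, MECOM by 0.95 and EMSY by 0.33 log2 units. Camera in limma gave adjusted p = 0.00175, and adjusted p = 0.136 with an estimated correlation. The median fell from 0.33 to 0.18 without both HGOV replicates 2, 4 and 6 and replicates 6 to 10. The list was then not called (camera in limma adjusted p = 0.108). CDKN2A, a cyclin-dependent kinase inhibitor, rose by 0.90 (limma adjusted p = 0.0103). MYC read -0.79 (limma adjusted p = 0.122) and ERBB2 -0.25 (limma adjusted p = 0.385). DUXAP10, a pseudogene transcript, rose by 2.06.

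Several gene groups were lower in HGOV. The p53 target genes, called DNA damage-response targets here, fell in 11 of 32 cases and rose in none (13 lower adjusted over the list alone). CDKN1A, which arrests the cell cycle, fell by 1.15 log2 units (SE 0.31, limma adjusted p = 0.0150), TRIM22 fell by 0.94, RPS27L fell by 0.93 and the repair factor XPC fell by 0.36. Motile cilium genes fell in 10 of 41 cases and rose in none (10 lower adjusted over the list alone): ARMC3 fell by 0.51, DNAI4 fell by 0.50, DNAH12 fell by 0.49 and DNAH7, an axonemal dynein, fell by 0.41. Genes of antigen presentation by MHC class II fell in 4 of 12 cases (6 adjusted over the list alone) with a median of -0.80, and HLA-DRA fell by 1.40, HLA-DQB1 fell by 1.37 (4 of its probe sets lower and 1 higher) and HLA-DPB1 fell by 1.31. Macrophage markers, which mark cells that carry these molecules, had a median of -0.05, with 1 of 21 higher and 1 lower. T and NK cell markers had a median of -0.05, with 1 of 24 higher and 5 lower (1 and 10 adjusted over the list alone). B and plasma cell markers had a median of -0.05, with none of 19 higher and 2 lower (2 lower adjusted over the list alone). Camera in limma gave adjusted p = 0.00225, adjusted p = 0.0120 and adjusted p = 0.0192 for the 3 lists, and with an estimated correlation adjusted p = 0.369, adjusted p = 0.950 and adjusted p = 0.950. MAPK pathway output genes, which follow the pathway often activated in low-grade serous tumours, fell in 4 of 18 cases. SPRY1 fell by 0.96, DUSP4 by 0.89, ETV4 by 0.54 and SPRY4 by 0.29. The MAPK list did not pass in camera (camera in limma adjusted p = 0.374). Fry, which does not compare a list with other genes, called it lower (fry in limma adjusted p = 0.0134). The 3' to 5' ratio averaged 1.63 in HGOV and 1.01 in LGOV, and it was above 2 only in HGOV replicates 2, 4 and 6. Without these arrays the class II list had a median of -0.80 (camera in limma adjusted p = 0.0302). Damage-response targets then had a median of -0.30 (camera in limma adjusted p = 0.00694), so both lists were still called. Without HGOV replicates 2, 4 and 6 the cilium list had a median of -0.19 against -0.23 with all arrays. It was then not called (camera in limma adjusted p = 0.0646). It was called without replicates 6 to 10 (camera in limma adjusted p = 0.000338) and without both sets (camera in limma adjusted p = 0.00294). The class II list had a median of -0.44 without replicates 6 to 10 (camera in limma adjusted p = 0.0270). It had the same median with the control probe split as a covariate (camera in limma adjusted p = 0.0611). With HGOV replicates 6 to 10 alone none of the 3 lists was called. Cilium had a median of -0.22 (camera in limma adjusted p = 0.305) and class II -1.28 (camera in limma adjusted p = 0.0887). Damage-response targets had -0.39 against -0.37 with all arrays (camera in limma adjusted p = 0.305).

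Genes with the largest falls in HGOV were ERP27, a chaperone of the endoplasmic reticulum, by -2.05 (SE 0.52, limma adjusted p = 0.0118), SOSTDC1, an inhibitor of bone morphogenetic protein signals, by -1.97, the secreted chaperone CLU by -1.78, ANXA1 by -1.66, TNFRSF11B by -1.57, the long noncoding RNA RMST by -1.53, ADGRG6 by -1.52 and ZBED2 by -1.42. Markers shared by serous tumours did not differ past the threshold: PAX8 read 0.26 (limma adjusted p = 0.593), WT1 -0.10 (limma adjusted p = 0.822), MUC16 -0.24 (limma adjusted p = 0.563), WFDC2 0.83 (limma adjusted p = 0.105) and ESR1 -0.38 (limma adjusted p = 0.363). Of the 9 probe sets of ESR1, 1 was higher.

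**Figure D3:**
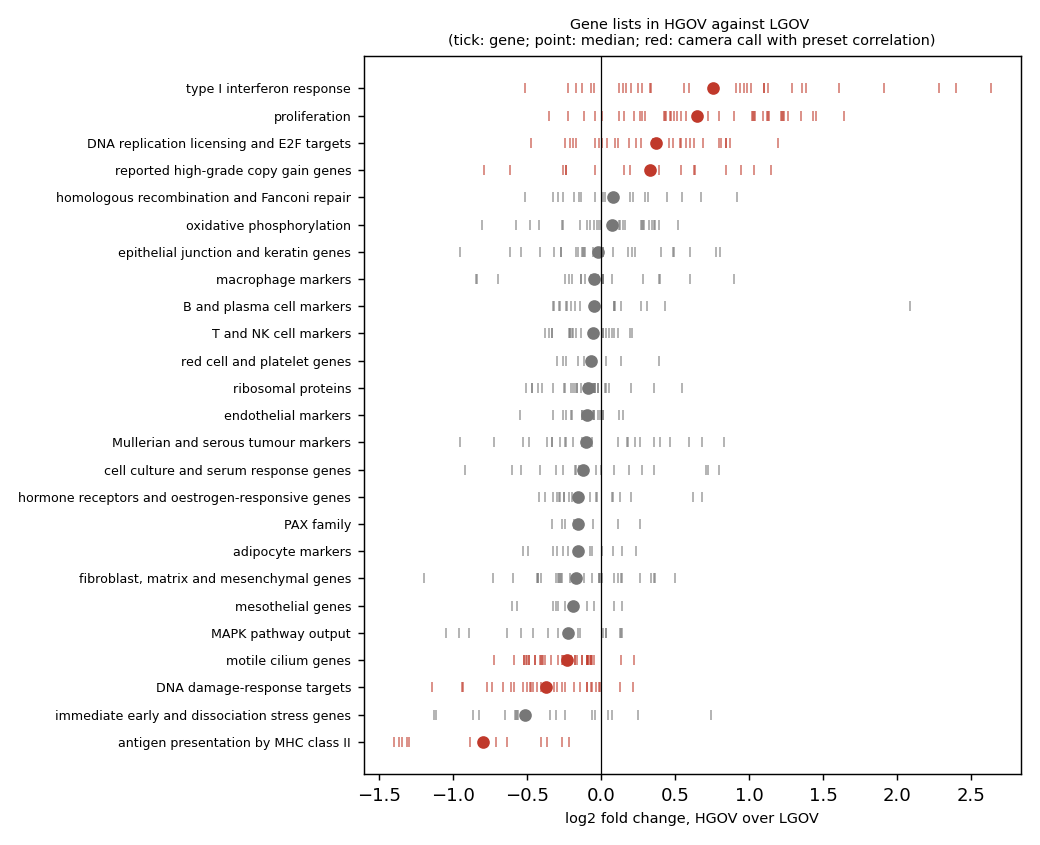
Log2 fold changes of HGOV over LGOV for the members of 25 gene lists; ticks are genes, points are medians, and red marks the 7 lists called by camera with the preset correlation. Interferon genes have the highest median, 0.76, and MHC class II genes the lowest, -0.80; with an estimated correlation no list was called.

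In all, 12703 of 54613 probe sets (23.3%) passed a limma adjusted p under 0.05 between HGOV and LGOV, 4099 higher and 8604 lower, with a median absolute log2 change of 0.33. At least 2-fold changes numbered 231, with 151 higher and 80 lower. Array scaling shifted the balance, with 5354 higher and 6408 lower after quantile normalization and 6051 higher and 5735 lower after median centring. Without HGOV replicates 6 to 10, which lay at one end of a control probe component, 606 probe sets passed (367 higher and 239 lower), and 14 of the 48 named genes that passed still did.

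The comparison of LGOV with HOSE set tumour samples against normal surface epithelium. The sample titles do not say whether HOSE was tissue or cultured cells. The changes therefore cannot be read as tumour against normal tissue alone. Epithelial and Mullerian genes were far higher in LGOV. Of 25 Mullerian and serous tumour markers, 21 rose and none fell (21 adjusted over the list alone): CD24 by 4.69 log2 units (SE 0.40, limma adjusted p = 1.35e-09), MUC16, which carries the CA-125 antigen, by 4.60, MUC1 by 4.33 and WFDC2 by 4.25, and CLDN4 was at least 14.5-fold higher, as all 3 HOSE arrays were at the floor. Of 31 epithelial junction and keratin genes, 25 rose and 2 fell (25 and 2 adjusted over the list alone), among them EHF by 3.92, GRHL2 by 1.89 and OVOL1 by 0.93. EPCAM, an epithelial adhesion molecule, was at least 30.6-fold higher and RHEX at least 40.4-fold higher, both at the floor in HOSE. SCNN1A, a sodium channel subunit, rose by 4.61 (2 probe sets higher and 1 lower) and the oestrogen receptor gene ESR1 by 4.04.

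All 12 MHC class II genes rose (12 adjusted over the list alone), with a median of 2.93; HLA-DRB1 rose by 4.71, HLA-DRA by 4.66, CTSS by 1.75 and CIITA, their transcriptional activator, by 1.75. Outside the list HLA-DRB6 rose by 5.07 and FOS by 5.01. Macrophage markers rose in 18 of 21 cases (19 adjusted over the list alone), including VSIG4 by 1.83, CYBB by 1.76, MSR1 by 1.47 and MS4A4A by 1.15. Motile cilium genes rose in 31 of 41 cases (31 adjusted over the list alone), including ARMC3 by 1.91, DNAI4 by 1.88, DNAH9 by 1.72 (1 probe set higher and 1 lower) and ENKUR by 1.47. Of all 54613 probe sets 28234 were called higher in LGOV, with a median change of 0.38 over all. The median change was 1.47 for macrophage markers and 0.99 for cilium genes. Cell content itself was not tested. Camera in limma gave adjusted p = 0.0278 for each of the Mullerian, epithelial and cilium lists, adjusted p = 0.0352 for MHC class II and adjusted p = 0.0115 for macrophages. With an estimated correlation these were adjusted p = 0.518 for the first pair and adjusted p = 0.610 for cilium, MHC class II and macrophages.

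Genes of the cell culture and serum response, high in cultured cells, fell in 10 of 19 cases and rose in 2 (10 and 2 adjusted over the list alone): DKK1 fell by 3.99, LOX, a collagen crosslinking enzyme, fell by 3.75 and TPM2 fell by 2.98 (2 probe sets lower and 1 higher), while PLAU rose by 1.39. Oxidative phosphorylation genes fell in 22 of 33 cases and rose in 1 (22 and 1 adjusted over the list alone), with ATP5PB -1.96, NDUFB3 -1.68 and CYCS -1.62 against NDUFS1 at 2.13 (3 probe sets higher and 1 lower). Proliferation genes fell in 17 of 40 cases and rose in 7 (17 and 7 adjusted over the list alone), with RRM2 at -1.82 and NDC80 at -1.62 against MKI67 at 1.21 and CENPA at 0.75. Camera in limma gave adjusted p = 0.000271 for culture genes, adjusted p = 1.23e-08 for oxidative phosphorylation and adjusted p = 0.000271 for proliferation; with an estimated correlation these were adjusted p = 0.518, adjusted p = 0.518 and adjusted p = 0.610. The largest falls were in MGARP (-5.28), BAMBI (-4.86), RGS4 (-4.68), the prostacyclin synthase gene PTGIS (-4.64), RNF128 (-4.53), CPA4 (-4.33), PRR9 (-4.32) and CYP1B1 (-4.29). MGARP, RNF128, PRR9 and DKK1 averaged 5.14 to 5.27 log2 units in LGOV, close to the floor of 5.11, so the floor limits the size of these falls. CDKN1A fell by 2.47.

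In total 37554 probe sets passed between LGOV and HOSE with limma, 28234 higher and 9320 lower, and 15982 by at least 2-fold (12040 higher and 3942 lower). The median change over all probe sets was 0.38 log2 units, and the array medians averaged 6.68 in LGOV against 6.11 in HOSE. Changes up to about the distance between these medians may reflect a shift of whole arrays. After quantile normalization 18244 were higher and 15315 lower (4602 and 5139 by at least 2-fold), and after median centring 14538 were higher and 24019 lower (2896 and 8698 by at least 2-fold). Camera called 15 lists (7 higher and 8 lower), 10 after quantile normalization (6 and 4) and 13 after median centring (8 and 5).

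HGOV was set against HOSE in the same way. Of 25 Mullerian and serous tumour markers 20 rose (21 adjusted over the list alone), WFDC2 by 5.08 log2 units (SE 0.54, limma adjusted p = 5.81e-08), CD24 by 4.87, MUC16 by 4.36 and CLDN3, a tight junction gene, by 3.74, and CLDN4 was at least 19.1-fold higher. Of 31 epithelial junction and keratin genes 25 rose and 3 fell (25 and 3 adjusted over the list alone): EPCAM was at least 46.4-fold higher and ESRP1, a splicing regulator of epithelial cells, at least 17.8-fold higher, EHF rose by 3.64 and GRHL2 by 1.72. RHEX was at least 41.9-fold higher, SPON1 rose by 4.68, SCNN1A by 4.57 and the immunoglobulin light chain gene IGKC by 4.27. MECOM rose by 3.46 and PAX8, a Mullerian transcription factor, by 1.25 (limma adjusted p = 0.0244).

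Most T and NK cell markers and endothelial markers read higher in HGOV, where 27501 of all 54613 probe sets were called higher. Their median changes were 0.84 log2 units for T and NK cells and 0.93 for endothelium, against 0.34 over all probe sets. Cell content itself was not tested. T and NK cell markers rose in 21 of 24 cases (21 adjusted over the list alone), CD8A by 1.39, CD3D by 1.33, KLRD1 by 1.17 and SH2D1A by 0.87. Endothelial markers rose in 17 of 20 cases (17 adjusted over the list alone), PECAM1 by 2.06, ROBO4 by 1.72, TEK by 0.95 and FLT1 by 0.94. Camera in limma gave adjusted p = 0.0165 for the Mullerian list, adjusted p = 0.0165 for the epithelial list, adjusted p = 0.00938 for T and NK cells and adjusted p = 0.00940 for endothelium; with an estimated correlation these were adjusted p = 0.441, adjusted p = 0.404, adjusted p = 0.661 and adjusted p = 0.518.

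Lower in HGOV were the mesothelial genes CPA4 (-4.50), BNC1 (-3.45), LRRN4 (-3.27) and UPK1B (-2.22), although only 4 of the 13 genes of that list fell and 2 rose (4 and 1 adjusted over the list alone). DNA damage-response targets fell in 19 of 32 cases and rose in 7 (19 and 7 adjusted over the list alone), with CDKN1A at -3.61, RPS27L at -3.53 and TIGAR at -3.10 against POLH at 1.57, a gene with 3 probe sets higher and 3 lower. Oxidative phosphorylation genes fell in 23 of 33 cases and rose in 1 (23 and 1 adjusted over the list alone), with ATP5PB -1.56, NDUFC1 -1.50 and UQCRC2 -1.34 (2 probe sets lower and 1 higher) against NDUFS1 at 2.20 (3 higher and 1 lower). Camera in limma gave adjusted p = 0.00505 for mesothelial genes, adjusted p = 3.08e-05 for damage-response targets and adjusted p = 1.49e-08 for oxidative phosphorylation; with an estimated correlation these were adjusted p = 0.404, adjusted p = 0.368 and adjusted p = 0.404. The largest falls were in MGARP (-4.98), BAMBI (-4.87), the osteoprotegerin gene TNFRSF11B (-4.79), PTGIS (-4.70), DPP4 (-4.64), ALDH1A3 (-4.58, with 1 probe set lower and 1 higher) and RGS4 (-4.57), and RNF128, at the floor in all 10 HGOV arrays, was at least 25.9-fold lower.

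In total 36210 probe sets passed between HGOV and HOSE with limma, 27501 higher and 8709 lower, and 13530 by at least 2-fold (9674 higher and 3856 lower). The median change over all probe sets was 0.34 log2 units, and the array medians averaged 6.62 in HGOV. After quantile normalization 16795 were higher and 14331 lower (3981 and 4439 by at least 2-fold), and after median centring 13328 were higher and 23120 lower (2644 and 7744 by at least 2-fold). Camera called 11 lists (5 higher and 6 lower), 11 after quantile normalization (7 and 4) and 12 after median centring (9 and 3). The mesothelial list was lost after median centring (camera in limma adjusted p = 0.0576).

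The comparisons of both grades with HOSE overlapped. Higher in both were 25568 probe sets against 14218 for independent lists, and lower in both 7702 against 1486. This balance turned with array scaling, with 14844 higher and 12888 lower in both after quantile normalization and 11640 higher and 21516 lower after median centring. Log2 fold changes correlated across probe sets at r = 0.954, where probe sets are not independent replicates. Unchanged groups simulated against the same 3 HOSE arrays gave r = 0.769 and no probe set called in both, on average over 20 simulations. The covariance was 0.725 against a simulated 0.0326. The simulations held the chance error of the HOSE mean, drawn for each probe set on its own. The values argue against such error as the main source of the overlap. A shift of whole HOSE arrays, by scaling or labelling run, was not simulated. The 3 HOSE arrays also cannot be split into parts of at least 2, so part of the excess overlap may come from such a shift of the shared arrays.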

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

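Tests of RNA quality, of the control-probe split, of labelling, of scaling and of macrophages were chosen after the results were seen; the counts over other splits of the arrays were planned. In 21 of 246 groups examined the most extreme array lay far from the rest, where chance gives about 5%, and the share here was 8.54%.

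In HGOV, replicate 1 had the highest PAX2 value on the specific probe set, 7.82 against 6.46 for the next array. Replicate 5 had the highest ERP27 (9.90, next 8.22) and DPP4 (8.10, next 6.17). Replicate 7 had the lowest RHEX (6.17, next 9.42) and the highest BAMBI (7.26, next 5.84). Replicate 9 had the lowest CLDN4 (8.10, next 9.12). Replicate 2 had the highest CIITA (7.84, next 7.26) and the highest signal of 18S ribosomal RNA (10.28, next 8.24).

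In LGOV, replicate 1 had the highest PGR (8.70, next 6.62), ARMC3 (8.20, next 7.87) and ATP5PB (10.23, next 9.45). Replicate 5 had the highest DUSP4 (9.46, next 7.78) and the lowest RHEX (6.22, next 10.06). Replicate 8 had the highest HLA-DOA (8.26, next 7.53) and the lowest WT1 (8.11, next 9.04). Replicate 10 had the highest ALDH1A3 (9.98, next 8.44) and BNC1 (5.69, next at the floor). Replicate 3 had the highest NDC80 (6.29, next 5.63), replicate 4 the highest RNF128 (6.29, next 5.34), replicate 9 the highest PRR9 (5.37, next 5.21) and replicate 2 the lowest CD3D (7.41, next 7.75).

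Among control probe sets that the comparisons do not use, Alu repeat signal averaged 14.07 in LGOV and 14.12 in HGOV against 13.18 in HOSE, and 18S ribosomal RNA signal averaged 8.33 in LGOV and 8.25 in HGOV against 6.64 in HOSE. Each difference had an exact two-sided permutation p = 0.00699, the smallest these groups can give.

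The number of probe sets that differ between HGOV and LGOV was examined first. Of 100 splits of the 20 tumour arrays, 1, the real one, gave as many (12703, highest other 9354). Chance is therefore unlikely, but 100 splits cannot exclude it. The splits also cannot tell grade from another difference between the arrays of the groups. RNA degradation in HGOV replicates 2, 4 and 6 is argued against as the whole cause, since 7763 probe sets passed without them. A difference of HGOV replicates 6 to 10, which lie at one end of a control probe component, stays open. Without them 606 passed, and 21552 passed with only those 5 HGOV arrays. When random sets of 5 HGOV arrays were left out, 7 of 100 gave a count as low as 606, and the median was 10290. Random sets can hold most of the same arrays, so this share cannot decide the question. Tumour grade, the biological difference the design names, is also open for the many small changes.

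The difference of both grades from HOSE was examined next. Of 100 splits, 1 gave as many probe sets for LGOV (37554, highest other 16927) and 1 for HGOV (36210, highest other 18556), each the real split. This makes chance unlikely without excluding it. Every other split mixed HOSE with tumour arrays, so the splits cannot tell why HOSE stands apart. After quantile normalization 9741 probe sets differed at least 2-fold between LGOV and HOSE, against 15982 before. Array scaling is therefore argued against as the whole cause. With the 3' to 5' ratio as a covariate 14892 differed at least 2-fold. That count cannot decide on 3' bias of the tumour RNA, since the ratio did not overlap between HOSE and tumours. The log2 ratio was at most 0.15 in HOSE and at least 0.51 in LGOV and 0.61 in HGOV. A separate labelling run of the HOSE arrays cannot be told apart from tissue, because the added poly-A transcripts were 2.04 log2 units higher in HOSE on average and every HOSE array lay apart. The tissue difference itself is open and untested. So is a difference in cell content or in cell culture, as the sample titles do not say how HOSE was obtained.

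The lower MHC class II genes in HGOV were examined last. Macrophage markers had a median change of -0.0469 (95% interval -0.20 to 0.08) against -0.80 for class II genes. The interval was taken over 21 marker genes, whose estimated correlation was 0.40, and does not measure the spread between tumours. It therefore weighs only weakly against fewer macrophages, which stay open. Fewer lymphocytes were not tested as a cause and stay open: T and NK cell markers were lower in 5 of 24 cases and B and plasma cell markers in 2 of 19, each with a median of -0.05. RNA degradation in HGOV replicates 2, 4 and 6 is argued against, with a median of -0.80 without these arrays. HGOV replicates 6 to 10 leave it open: the median was -0.44 without them, where the list was still called (camera in limma adjusted p = 0.0270). The list was also called without both sets (median -0.44, camera in limma adjusted p = 0.0230). The call was lost with the split as a covariate (camera in limma adjusted p = 0.0611). A lower expression in the tumour cells may be a further explanation, and no test here separated it.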

How the results depend on the processing

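Settings that leave out or adjust for HGOV arrays were chosen after the data were seen. Over all settings, 6541 values of named genes and 1314 of gene lists kept their side of the threshold (38 of them changed sign while past it in neither setting), 254 and 44 fell below it, 67 and 0 rose past it, and 5 and 2 changed sign. For a list the sign is the direction camera gave, not that of the median of its genes. Causes were not tested. Signal near the floor limits PAX2 on its specific probe set.

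Between HGOV and LGOV, 12703 probe sets (231 by at least 2-fold) became 2927 (120) at adjusted p under 0.01, 4537 (60) with genes in place of probe sets, 7763 without the low 5' HGOV arrays, 606 (99) without replicates 6 to 10, 21552 (792, and 4 lists) with only those, 309 (65) with the split as covariate and 95 (40) without both sets. With each array left out, the count ran from 9489 (HGOV replicate 7) to 16018 (HGOV replicate 3), 2-fold counts from 176 to 335, and lists from 7 to 8. LGOV against HOSE gave 24943 probe sets without dim ones, 14241 (4458) as genes and 9741 2-fold changes after quantile normalization; HGOV against HOSE gave 13814 (3615) and 8420. Their overlap was 12737 as genes. Camera with an estimated correlation called 0 lists in each comparison, and fry 19 for HGOV against HOSE. With each array left out, LGOV against HOSE ran from 34398 to 37918 (15056 to 16445 2-fold, 14 to 15 lists), HGOV against HOSE from 32632 to 36658 (12716 to 13953, 11 to 12 lists) and the overlap from 29897 to 33709.

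PAX2 on the specific probe set fell below the threshold between HGOV and LGOV at -1.60 in a fit of 2 groups (limma adjusted p = 0.0649), without a trend and with the replicate block (limma adjusted p = 0.0743), at -1.59 with the 3' ratio, -1.31 without HGOV replicates 6 to 10 or with the split as covariate and -0.83 without both sets; each array left out gave -1.85 to -1.31. Against HOSE, where ties at the floor kept the permutation test from passing, LGOV rose past the threshold at 2.98 with a floor of 1 (exact permutation p = 0.00699) and read 2.23, below it, in a fit of 2 groups; HGOV rose past it at 1.36 with a floor of 1 (exact permutation p = 0.00699) and 0.92 without replicates 6 to 10 (exact permutation p = 0.0357). Each array left out gave 1.95 to 2.48 and 0.40 to 0.70, past the threshold without LGOV replicate 5 or 8 for LGOV and without HGOV replicate 8 or 9 for HGOV (exact permutation p = 0.0364 each), the arrays at the floor. On the x probe set, LGOV minus HOSE was 0.18 after quantile normalization and 0.17 after centring, HGOV minus HOSE -0.10 and -0.11, both reversed, and 0.56 without both sets. HGOV minus LGOV was -0.26 with the split as covariate and -0.18 without both sets. Each array left out gave -0.37 to -0.30 between grades, 0.70 to 0.76 for LGOV and 0.37 to 0.43 for HGOV.

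For ribosomal protein genes against HOSE, camera's direction turned from lower to higher after quantile normalization. The size of the median was then 0.0576 in LGOV and 0.0966 in HGOV, and neither was called. The genes themselves need not have turned, since their median in LGOV was already 0.04 in the main setting. With genes in place of probe sets the sign changed for MKI67 between grades (0.29), ERBB2 in LGOV (-0.0268) and POLH in HGOV (-0.0737). Replicate numbers are shared by the groups but did not pair the arrays: deviations of same-numbered LGOV and HGOV arrays correlated from -0.23 to 0.22, and 1 of 10 LGOV arrays correlated best with its own number. The replicate block gave 10292 probe sets between grades, 35661 and 34505 against HOSE.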

Other observations

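The hormone receptor and oestrogen-responsive list did not pass in camera between LGOV and HOSE (camera in limma adjusted p = 0.447). Of its 24 members 15 rose and 3 fell (16 and 3 adjusted over the list alone). Fry, which does not compare a list with other genes, called it higher (fry in limma adjusted p = 4.76e-10). Immediate early genes read a median of 1.46 in LGOV over HOSE, 11 of 19 higher and 1 lower, with camera adjusted p = 0.871 in limma. Fry called this list higher too (fry in limma adjusted p = 0.0159). Between the grades, T and NK cell markers were lower in 5 of 24 cases and higher in 1 (10 and 1 adjusted over the list alone), with camera adjusted p = 0.684 in limma. Homologous recombination and Fanconi repair genes split evenly between HGOV and LGOV, 4 of 21 higher and 4 lower, with camera adjusted p = 0.181 in limma.

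A hypothesis that a shared programme of genes follows PAX2 across the 10 LGOV arrays was tested by a regression in limma on the specific PAX2 probe set, a test chosen after its result was seen. It gave 0 of 54611 probe sets of other genes at an adjusted p under 0.05, and 4316 at an unadjusted p under 0.05. The smallest adjusted p, 0.154, was shared by PDCD2, MAP7 and PNISR, which were picked after their values were seen. With 10 arrays this leaves such a programme open.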
